A study of Rattus norvegicus with 9 samples.

How the data were processed

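Messenger RNA was sequenced from the spinal cord of female Wistar rats, aged 8 weeks and weighing 200 to 230 g. There were 9 libraries in 3 groups of 3. In the Sham group the lamina was opened and the cord left intact. In the C_Spinal group the cord was injured and the rats received distilled water by gavage. In the T_Spinal group the cord was injured and the rats received 3 mL of Modified Erxian Decoction, a traditional Chinese herbal mixture, by gavage each day. The labels give no time after injury, no injury method or level, no dissected length of cord, no sequencing batch, and no statement on whether the 3 libraries of a group came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical.

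Per the labels, total RNA with an integrity number above 7.0 was extracted with Trizol. Poly(A) RNA from 1 µg was made into stranded paired-end libraries with inserts of 300 ± 50 bp. The submitters named HISAT and StringTie for mapping and quantification, without versions. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds whole-number counts per gene for each library and the deposited FPKM (fragments per kilobase of transcript per M fragments), in which genes with a count of 0 are listed at a small constant. Chromosome, start and end of each gene are those of the deposited table, and so are the KEGG pathway assignments. Of its 32623 genes, 22666 had a count in at least 1 library and 11659 had a placeholder in place of a gene symbol. Total counts (M, for 1e+06) per library were 69.8, 69.6 and 57.0 M in Sham, 59.1, 59.8 and 67.3 M in C_Spinal, and 61.8, 69.4 and 69.1 M in T_Spinal.

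Genes with a mean FPKM of at least 1 over the 9 libraries were tested, which left 14791 genes holding 99.7% of the counts. The counts were scaled by the trimmed mean of M values (TMM) and fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, with all 9 libraries in a single fit and no covariate. The 3 contrasts were C_Spinal against Sham, T_Spinal against C_Spinal and T_Spinal against Sham. Genes were called at a two-sided Benjamini-Hochberg adjusted p below 0.05 with no minimum fold. The plan written before the data were examined named limma on log2(FPKM + 1) for a table of FPKM, and edgeR quasi-likelihood in its place if counts were present. The table held counts, so edgeR is the reported test and limma an alternative. Tables were read with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

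The contrasts, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 40 lists cover homeostatic microglia, phagocytic macrophages, neutrophils, lymphocytes, reactive and homeostatic astrocytes, myelin and oligodendrocytes, oligodendrocyte precursors, neurons, motor neurons, sensory ganglion neurons, synaptic receptors and channels, extracellular matrix and scar, and chondroitin sulfate proteoglycans with growth inhibitors. They also cover regeneration-associated genes, neurotrophic factors, the PI3K-AKT core pathway, apoptosis, cytokines and NF-kappaB, interferon response, antigen presentation, complement, cell cycle, lysosome, cholesterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, immediate early genes, heat shock, and iron and oxidative stress. The others are endothelium and pericytes, ependymal cells, Schwann cells, red blood cells, skeletal muscle, adipose tissue, meninges, bone and cartilage, mitochondrially encoded genes and ribosomal proteins. Symbols were matched exactly apart from case. A few symbols, among them Uqcrb, Crabp2, Rpl32 and Rps10, each matched 2 genes of the table, and both were kept. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 40 lists of each contrast. The alternatives were camera with an estimated correlation and fry, whose p says whether a list's genes move on balance and compares them with no other genes. KEGG pathways with at least 10 tested genes were tested in the same way, which was decided after the data were seen.

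Genes named per contrast were taken from a fixed set, of which Gfap, Aif1, Mbp, Snap25, Gap43, Bdnf, Pik3ca, Akt1, Mtor, Bcl2 and Bax are given here. To these were added the 5 largest rises and 5 largest falls among called genes with a symbol, non-overlapping groups and a mean FPKM of at least 1 in the higher group. Then followed up to 3 leading members of each called list, in order of the list test, until about 30 genes were reached. Any other gene named was chosen after its values were seen. Where a group had no counts in any library, the fold is a lower bound against a floor of 3 counts per library, which covers counting error only.

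Each library was also placed on an injury axis, the mean of log2(FPKM + 1) over injury-called genes signed by the direction of the injury change, with the Sham mean set to 0 and the C_Spinal mean to 1. The genes and scale for a Sham or C_Spinal library came from a fit without it. T_Spinal was compared with C_Spinal by an exact two-sided permutation test. The injury and treatment contrasts share the C_Spinal libraries, so their fold changes were also compared in simulated series with no effect and in series with the injury effect alone, 50 of each. The plan named 100 simulated series with normal errors; negative binomial counts with each gene's fitted quasi-likelihood variance took their place because the table held counts.

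The pipeline was tested on simulated data of 14791 genes with the same variances, in which 200 genes were changed, 50 at each of 4 sizes. Between T_Spinal and C_Spinal, 18% of genes changed 1.2-fold were recovered, 68% at 1.5-fold, 76% at 2-fold and 96% at 4-fold, with 7 false calls. Between T_Spinal and Sham the shares were 10%, 62%, 76% and 96%, with 8 false calls. With the larger gene-wise (tagwise) variances of a first version, 4% were recovered at 1.2-fold in both contrasts. The 2-fold genes with a fitted coefficient of variation under 10% were recovered in 27 of 27 cases, against 11 of 23 with a larger one. In the real data 38.6% of genes were called in T_Spinal against C_Spinal and 71.5% in T_Spinal against Sham. The adjusted p depends on the share of changed genes, so these recoveries hold only for a series with few of them. A planned bound on the share recovered at 2-fold was missed and was replaced by checks on bias, false calls and the less variable genes. Alternatives changed the filter, scaling, tool, pseudocount, weights, minimum fold, replicate number as a block, and the libraries included. limma on log2(FPKM + 1), DESeq2 1.42.0 and total-count scaling were added after seeing the data. No library was left out of the reported fit.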

Results

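Spinal cord RNA was compared between rats with an opened lamina alone (Sham), rats with cord injury given water (C_Spinal) and rats with cord injury given Modified Erxian Decoction (T_Spinal), with 3 libraries per group. Depth averaged 65.5 M counts per library in Sham, 62.0 M in C_Spinal and 66.8 M in T_Spinal (M, counts in units of 1e+06). The libraries separated by group: Spearman correlations of expression across genes were 0.991 to 0.993 within groups, 0.973 to 0.975 between C_Spinal and T_Spinal, 0.850 to 0.852 between Sham and T_Spinal and 0.805 to 0.810 between Sham and C_Spinal. Genes are not independent replicates in such correlations. The myelin transcript Mbp alone took 5.29% ± 0.0956 (SD, n = 3) of all counts in Sham, 1.66% ± 0.0254 in C_Spinal and 1.78% ± 0.0193 in T_Spinal. Apoe, which carries lipids and is made by astrocytes and macrophages, took 0.227% ± 0.00876, 2.92% ± 0.155 and 2.34% ± 0.107 in the same order. The share of mitochondrially encoded transcripts was 8.81% ± 0.674 in Sham, 6.24% ± 0.208 in C_Spinal and 5.08% ± 0.0894 in T_Spinal.

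The comparison of C_Spinal with Sham asks how injured cord, from rats given water by gavage, differed from intact cord. Transcripts of neurons, synapses, myelin and cholesterol synthesis fell, while those of phagocytes, the complement system, interferon signalling, scar matrix and reactive astrocytes rose. Snap25, a protein of synaptic vesicle fusion, went from an FPKM of 549.7 ± 19.6 (SD, n = 3) in Sham to 31.5 ± 1.91 in C_Spinal, a log2 fold change of -4.25 (SE 0.0511, adjusted p = 1.08e-12). Cd68, a lysosomal protein of phagocytes, went from 2.22 ± 0.763 to 625 ± 11.7, a log2 fold change of 7.99 (SE 0.199, adjusted p = 1.08e-10). Of 14791 genes tested with edgeR, 5632 were higher and 5526 lower in C_Spinal, 2648 and 2271 of them by at least 2-fold. The groups did not overlap for 9896 genes (66.9%, against 10% by chance). Of the calls 50.5% were higher, against 57.7% with total-count scaling alone changed. With limma in place of edgeR the share was 57.8% on log2(FPKM + 1) and 45.4% after a rescaling of each library's FPKM to a common sum.

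Neuronal loss of signal after injury was broad. All 24 neuron genes fell, with a median log2 fold change of -3.61 (camera adjusted p = 3.00e-43). The leading members were Slc6a5, the neuronal glycine transporter, at -5.61 (SE 0.110, adjusted p = 2.19e-11), Glra1, a glycine receptor subunit, at -5.31 (SE 0.181), and Slc32a1, which loads GABA and glycine into vesicles, at -4.58 (SE 0.133). All 34 tested synaptic receptors and channels fell (median -2.98, adjusted p = 4.94e-29), as did all 6 tested motor neuron genes (median -2.60, adjusted p = 0.000420). The 5 largest falls were Glra2, another glycine receptor subunit, at -7.26 (SE 0.526, adjusted p = 4.34e-07), Creg2 at -6.05, Plcxd2 at -5.72, Zdhhc22 at -5.70 and the NMDA receptor subunit Grin2a at -5.69. All 24 myelin genes fell (median -1.29, adjusted p = 4.26e-16), Mbp at a log2 fold change of -1.79 (SE 0.0210). All 24 genes of cholesterol synthesis fell (median -2.80, adjusted p = 1.06e-30). Hmgcs1, which makes HMG-CoA, was at -4.00 (SE 0.0405, adjusted p = 3.89e-13). Of 17 homeostatic astrocyte genes, 12 fell and 2 rose (median -0.86, adjusted p = 3.60e-05).

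Phagocyte and immune genes rose after injury. Of 24 phagocytic macrophage genes, 23 rose and 1, Arg1, fell (median 3.34, adjusted p = 3.07e-37). Mmp12, the macrophage elastase, rose by 9.99 (SE 0.413) and Gpnmb, a glycoprotein of lipid-laden phagocytes, by 7.40 (SE 0.129). The matrix protease Mmp7 had no counts in any Sham library and an FPKM of 22.5 ± 2.01 in C_Spinal, at least 518-fold higher (adjusted p = 9.12e-10). RT1-M2, the chemokine receptor Cxcr1, the lectin-like receptor Ly49s7 and the proton pump subunit Atp6v0d2 were also without counts in Sham, and were at least 167-, 159.7-, 152- and 128-fold higher. RT1-M2 and Ly49s7 belong to families of near-identical genes, so which member was counted is uncertain. Rises also came in 20 tested complement genes (17 up, 2 down, median 3.35, adjusted p = 2.53e-25), 25 interferon-response genes (24 up, 1 down, median 2.63, adjusted p = 2.18e-26) and 20 antigen presentation genes (19 up, median 2.25, adjusted p = 1.22e-08). All 27 tested cytokine and NF-kappaB genes rose (median 2.59, adjusted p = 1.54e-07). Of 29 lysosomal genes, 24 rose and 2 fell (median 1.96, adjusted p = 1.29e-23). Of 15 homeostatic microglia genes, 11 rose and 3 fell (median 0.70, adjusted p = 3.71e-06); Aif1, a marker of microglia and macrophages, rose by 2.87 (SE 0.0800), while P2ry12, Selplg and Sall1, looked up afterwards, fell. All 4 tested neutrophil genes rose, with a fitted median of 8.56, or 6.22 with genes absent from Sham placed at their bounds (adjusted p = 0.000336). Without the expression minimum, 7 of 12 neutrophil genes rose and none fell (median 4.14).

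Scar and support tissue genes rose as well. Of 27 matrix and scar genes, 26 rose and none fell (median 3.39, adjusted p = 2.90e-49), led by the collagen cross-linking enzyme Lox at 5.01 (SE 0.103, adjusted p = 2.88e-11), the protease inhibitor Timp1 at 4.59 (SE 0.0676) and the adhesion protein Thbs1 at 4.51 (SE 0.0957). All 18 tested reactive astrocyte genes rose, Timp1 again among them (median 3.07, adjusted p = 1.29e-23), and Gfap, the intermediate filament of astrocytes, rose by 0.89 (SE 0.0200). Meningeal genes (10 of 12 up, median 3.29, adjusted p = 1.67e-10) and Schwann cell genes (15 of 16 up, 1 down, median 1.03, adjusted p = 0.000653) rose with them. The labels give no dissected region, so a difference in dissection between Sham and C_Spinal cannot be told apart from injury for these lists. Cell cycle genes rose (24 of 27 up, 2 down, median 1.80, adjusted p = 0.000761), and so did all 50 ribosomal protein genes (median 1.29, adjusted p = 6.77e-18). Of 26 apoptosis genes, 20 rose and 4 fell (median 1.13, adjusted p = 0.000481). The largest rise, picked out afterwards, was the death-blocking Bcl2a1 of leukocytes at 5.34. The death effector Bax rose by 1.26, and Bcl2, which blocks death, had 0.23 (SE 0.267, adjusted p = 0.455). Iron and oxidative stress genes rose (16 of 23 up, 5 down, median 0.64, adjusted p = 3.38e-06). In the adipose list 3 of 4 genes rose and 1 fell (median 3.72, adjusted p = 0.00371), and without the expression minimum 3 of 9 rose and 1 fell (median 0.43). Its leading members Fabp4 and Cfd are also made by macrophages, and the list call ended with limma on log2(FPKM + 1) (adjusted p = 0.137). Over the alternatives the adjusted p ranged from 7.17e-10 with fry, which compares the list with no other genes, to 0.221.

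Calls of 5 further lists were lost when the correlation between genes was estimated. These were endothelium and pericytes (12 of 18 up, 2 down, median 0.46; adjusted p = 0.0769 with an estimated correlation), chondroitin sulfate proteoglycans and growth inhibitors (7 of 22 up, 14 down, median -0.48; adjusted p = 0.135 with an estimated correlation) and oxidative phosphorylation (4 of 33 up, 23 down, median -0.27; adjusted p = 0.107 with an estimated correlation). The others were red blood cells (5 of 6 down, median -1.47, adjusted p = 0.127 with an estimated correlation) and mitochondrially encoded genes (12 of 13 down, median -0.63, adjusted p = 0.503 with an estimated correlation). The other 23 of 28 called lists kept their call, at adjusted p values of 0.000162 to 0.0359 with an estimated correlation. Lists not called were oligodendrocyte precursors (2 up and 8 down of 12), lymphocytes (2 up of 3), regeneration-associated genes (10 up and 10 down of 21), neurotrophic factors (8 and 8 of 20), the PI3K-AKT core pathway (19 and 21 of 47), glycolysis and hypoxia (5 and 13 of 21), immediate early genes (8 and 7 of 18), heat shock (11 and 4 of 18), ependymal cells (5 and 1 of 11), sensory ganglion neurons (1 and 2 of 3), skeletal muscle (1 and 3 of 6), and bone and cartilage (2 and 2 of 5). Their adjusted p values ran from 0.113 to 0.756. Only 3 of 19 lymphocyte genes and 4 of 13 neutrophil genes reached the expression minimum; without it, 12 of 18 lymphocyte genes rose and none fell. Adjusted over the list alone, the counts up and down differed for cell cycle 25 and 2, immediate early genes 9 and 7, iron and oxidative stress 17 and 5, meninges 11 and 0, and were equal to those above for the other lists. Of single genes, Gap43, a growth cone protein, fell by 0.39 (SE 0.0348), and Bdnf, below the expression minimum with a mean FPKM of 0.288, had -0.64 (SE 0.239, adjusted p = 0.0409 with no minimum).

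**Figure D1:**
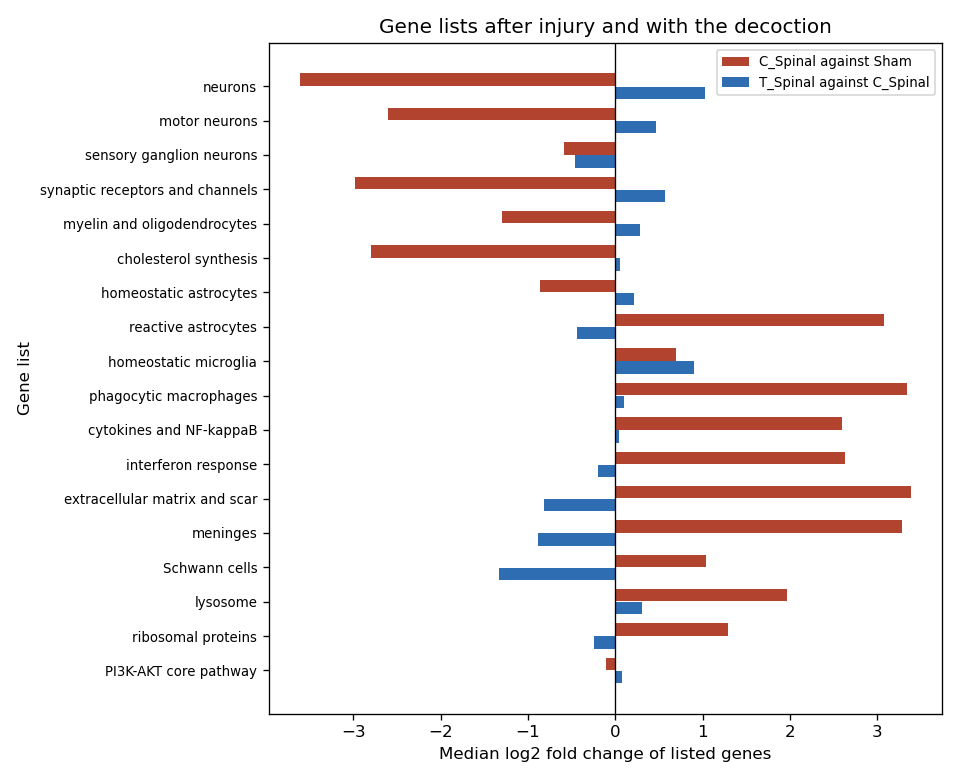
Bars show the median log2 fold change of each of 18 gene lists, on the vertical axis, for C_Spinal against Sham and for T_Spinal against C_Spinal. The neuron bar lies at -3.61 after injury and 1.02 with decoction, the matrix and scar bar at 3.39 and -0.82, and cholesterol synthesis at -2.80 and 0.05.

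The comparison of T_Spinal with C_Spinal asks what the decoction changed in the injured cord. Genes of neurons, synapses, homeostatic microglia and myelin were higher in T_Spinal, and genes of scar matrix, Schwann cells and meninges were lower. Snap25 was at 65.2 ± 1.09 FPKM (SD, n = 3) in T_Spinal against 31.5 ± 1.91 in C_Spinal, a log2 fold change of 1.01 (SE 0.0456, adjusted p = 2.62e-07). Thbs1, an adhesion protein of scars and platelets, was at 7.11 ± 0.556 against 50.8 ± 0.593, a change of -2.87 (SE 0.0873, adjusted p = 2.24e-08). The differences were smaller than those of injury: edgeR called 3057 genes higher and 2650 lower, with a median absolute log2 fold change of 0.38 against 0.86 after injury, and 234 and 264 of them passed 2-fold. The groups did not overlap for 5359 genes (36.2%, against 10% by chance). Under the common-sum rescaling, with limma, 4864 were higher and 1574 lower, so that 75.6% of calls were higher against 53.6% in the reported fit, with a median log2 fold change of 0.11 over all genes.

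Matrix and scar genes fell together. All 27 tested were lower in T_Spinal (median -0.82, adjusted p = 3.31e-63), with Lox at -1.74 (SE 0.0863) and Col3a1, a fibrillar collagen, at -1.30 (SE 0.0407). Of 16 Schwann cell genes, 14 fell and none rose (median -1.33, adjusted p = 4.16e-37). Prx, which links Schwann cells to their matrix, had a log2 fold change of -1.99 (SE 0.0364) and Ncmap, a small membrane protein of peripheral myelin, of -2.17 (SE 0.118). Of 12 meningeal genes 11 fell (median -0.88, adjusted p = 7.84e-12), counting a second copy of Crabp2 that is uncertain, since only C_Spinal replicate 3 of its group had counts. That call ended without this library (log2 fold change 0) and under most other alternatives. Endothelial and pericyte genes fell (9 of 18 down, 1 up, median -0.32, adjusted p = 0.000588). Reactive astrocyte genes fell (11 of 18 down, 1 up, median -0.44, adjusted p = 1.22e-07), whereas Gfap itself rose by 0.09 (SE 0.0198, adjusted p = 0.00588). Neutrophil genes fell in 3 of 4 cases and rose in 1 (median -1.58, adjusted p = 0.00104), with the calcium-binding protein S100a9 at -3.06 (SE 0.468). Without the expression minimum, 4 of 12 neutrophil genes fell and 1 rose (median -1.33). All 4 tested adipose genes fell (median -0.68, adjusted p = 0.00104), and 4 of 9 without the minimum (median -0.31). The other largest falls were Mmp7 at -3.10 (SE 0.127, adjusted p = 1.30e-06), Shisa3 at -2.82 and the growth factor Clec11a at -2.78.

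Genes of neurons, homeostatic microglia and myelin rose. All 24 neuron genes were higher in T_Spinal (median 1.02, adjusted p = 7.06e-30), with Slc6a5 at 1.99 (SE 0.101), Glra1 at 1.91 (SE 0.167) and the neuronal splicing factor Rbfox3 at 1.46 (SE 0.101). Slc6a5 still stood at 2.45 ± 0.0692 FPKM, against 0.603 ± 0.108 in C_Spinal and 27.1 ± 1.11 in Sham. Of 34 synaptic genes 30 rose and none fell (median 0.57, adjusted p = 5.56e-18). Of 15 homeostatic microglia genes 12 rose and 1 fell (median 0.90, adjusted p = 5.19e-23): the surface receptors Gpr34, Cx3cr1 and P2ry12 rose by 1.51, 1.48 and 1.44. Cx3cr1, the fractalkine receptor, was at 21.9 ± 1.67, 34.2 ± 1.58 and 97.8 ± 0.932 FPKM in Sham, C_Spinal and T_Spinal. Aif1, also of that list, had 0.05 (SE 0.0733, adjusted p = 0.637). Myelin genes rose (19 of 24 up, 1 down, median 0.29, adjusted p = 2.92e-08), as did homeostatic astrocyte genes (11 of 17 up, 2 down, median 0.21, adjusted p = 0.00165) and lysosomal genes (18 of 29 up, 3 down, median 0.30, adjusted p = 3.43e-07). The rise of Mbp was small (0.07, SE 0.0204, adjusted p = 0.0275), and its call ended under several alternatives. Among them were the omission of C_Spinal replicate 1, 2 or 3 (log2 fold changes 0.08, 0.06 and 0.06) or T_Spinal replicate 1 (0.06) and the fit with no expression minimum (0.07), with adjusted p values of 0.0660 to 0.0888 in these. The call was kept under the rescalings of the libraries. The largest rise was Ifit1, an interferon-induced antiviral protein, at 2.51 ± 0.263 FPKM in Sham, 0.206 ± 0.104 in C_Spinal and 22.5 ± 0.696 in T_Spinal, a change of 6.71 (SE 0.256, adjusted p = 9.37e-08). Part of its reads could belong to related Ifit genes. Next came Pld5 at 3.09, the transcription factor Elk4 at 2.96, the Fc receptor-like Fcrl2 at 2.87 and the centromere protein Cenpp at 2.46.

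Calls of 7 further lists were lost with an estimated correlation. Ribosomal protein genes (32 of 50 down, median -0.24) had adjusted p = 0.0896 with an estimated correlation, and mitochondrially encoded genes (12 of 13 down, median -0.35), which moved with the lower mitochondrial share of counts, had adjusted p = 0.260 with an estimated correlation. Oligodendrocyte precursor genes (7 of 12 up, 1 down, median 0.38) had adjusted p = 0.208 with an estimated correlation, complement genes (9 of 20 up, 5 down, median 0.18) 0.120, antigen presentation genes (8 of 20 up, 3 down, median 0.28) 0.178 and red blood cell genes (4 of 6 up, median 0.40) 0.199. Hemoglobin genes are near-identical copies, so their single values are uncertain. Chondroitin sulfate proteoglycans and growth inhibitors (11 of 22 up, 3 down, median 0.18, adjusted p = 0.0496) had adjusted p = 0.225 with an estimated correlation. That call also ended under other alternatives, among them the common-sum rescaling (median 0.28, adjusted p = 0.0613) and the omission of Sham replicate 1 or 2, C_Spinal replicate 2 or 3, or T_Spinal replicate 1 or 2 (adjusted p values of 0.0582 to 0.0721). The range over all alternatives was 0.000163, with fry, to 0.225, with camera and an estimated correlation. The other 13 of 20 called lists kept their call, at adjusted p values of 0.000265 to 0.0427 with an estimated correlation. Closest to 0.05 were lysosome at 0.0427, homeostatic astrocytes at 0.0411, and neutrophils and adipose tissue at 0.0405 each. Not called were phagocytic macrophages (9 up and 7 down of 24), lymphocytes (0 and 0 of 3), motor neurons (3 and 0 of 6), apoptosis (2 and 5 of 26), interferon response (3 and 12 of 25), cell cycle (3 and 2 of 27), cholesterol synthesis (5 and 2 of 24), oxidative phosphorylation (5 and 14 of 33), glycolysis and hypoxia (9 and 4 of 21), immediate early genes (5 and 6 of 18), ependymal cells (0 and 2 of 11), skeletal muscle (1 and 1 of 6), and bone and cartilage (1 and 2 of 5). Lists whose median and test differed in sign, also without a call, were regeneration-associated genes (7 and 7 of 21, median 0.06, test down), neurotrophic factors (4 and 6 of 20, 0.08, down), cytokines and NF-kappaB (5 and 5 of 27, 0.04, down), heat shock (7 and 5 of 18, 0.03, down), iron and oxidative stress (3 and 8 of 23, 0.00, down) and sensory ganglion neurons (1 and 1 of 3, -0.46, up). The mean of the interferon list was 0.09 although its median was -0.20. Adjusted over the list alone, the counts up and down differed for reactive astrocytes 1 and 12, myelin and oligodendrocytes 19 and 2, oligodendrocyte precursors 8 and 1, motor neurons 4 and 0, chondroitin sulfate proteoglycans and growth inhibitors 13 and 4, regeneration-associated genes 8 and 8, neurotrophic factors and receptors 5 and 7, interferon response 3 and 13, antigen presentation 9 and 4, cell cycle 2 and 1, lysosome 20 and 3, oxidative phosphorylation 5 and 16, immediate early genes 5 and 7, iron and oxidative stress 4 and 8, sensory ganglion neurons 1 and 2, red blood cells 5 and 0, meninges 0 and 12, ribosomal proteins 0 and 37, and were equal for the other lists. Among apoptosis genes, Bax was lower at -0.52 (SE 0.0750), while Bcl2 had 0.03 (adjusted p = 0.937). Gap43 rose by 0.33 (SE 0.0348), and Bdnf had 0.17 (adjusted p = 0.696 with no expression minimum).

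The series title names PI3K-AKT signalling, the kinase cascade that carries growth factor signals to protein synthesis and survival. Only transcript levels were measured here, so the values below do not show whether the kinases were more or less active. Of the 47 genes of its core list, 17 rose and 8 fell in T_Spinal against C_Spinal (median 0.08; camera adjusted p = 0.254), and the same numbers passed when adjusted over the list alone. The adjusted p was 0.0458 under the common-sum rescaling, where the list median of 0.18 lay beside a median of 0.11 over all genes, and ranged from 0.00187 with fry to 0.454 over the alternatives. The catalytic subunit Pik3ca had 0.09 (SE 0.0474, adjusted p = 0.160), called only under that rescaling (0.20), with adjusted p values from 0.0133 to 0.402 over the alternatives. The kinase Akt1 had -0.02 (SE 0.0260, adjusted p = 0.599), with a called change of the other sign, 0.10, under that rescaling, and adjusted p values from 0.0120 to 0.932 over the alternatives. Mtor, a kinase further down the pathway, rose by 0.29 (SE 0.0467, adjusted p = 0.000869). Members chosen after their values were seen were Pik3cg at 0.94, Pik3cd at 0.55 and Inpp5d at 0.67, all best known from blood cells, and Ddit4, an inhibitor of mTOR, at -1.42. After injury, Pik3ca was lower at -0.35, Akt1 higher at 0.28 and Mtor lower at -0.72. The core list had a median of -0.11, a mean of 0.17 and an upward test (adjusted p = 0.466). The wider KEGG pathway of 269 tested genes was called up after injury (134 up, 100 down, camera adjusted p = 0.00486). It was also called up in T_Spinal against Sham (130 up, 97 down, adjusted p = 0.00610). Both calls were lost with an estimated correlation (adjusted p = 0.0689 and 0.0730). In T_Spinal against C_Spinal 72 rose and 74 fell, without a call (camera adjusted p = 0.170, or 0.343 with an estimated correlation). The pathway's 46 matrix and integrin members overlapped the matrix list and were separated after the data were seen. In that contrast they had 8 up and 25 down (median -0.39). The remaining 223 had 64 up and 49 down (median 0.04).

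**Figure D2:**
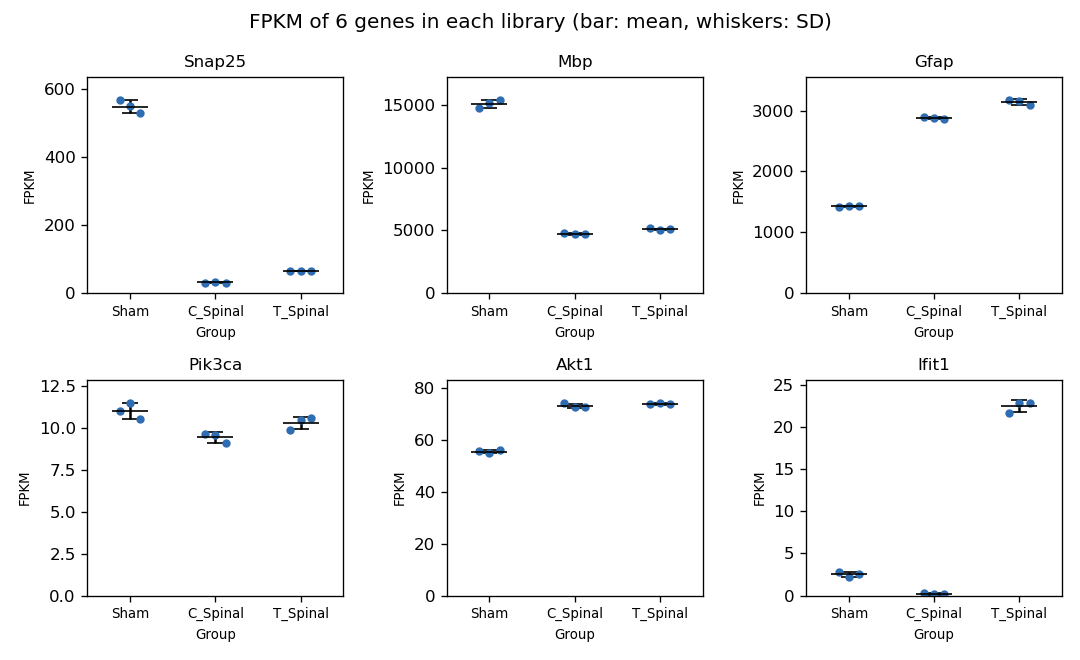
Points show the FPKM of each library, with group mean and SD, for Snap25, Mbp, Gfap, Pik3ca, Akt1 and Ifit1 in Sham, C_Spinal and T_Spinal. Snap25 averages 549.7, 31.5 and 65.2 in that order, Akt1 55.5, 73.1 and 74.0, and Ifit1 2.51, 0.206 and 22.5. Against C_Spinal, Akt1 in T_Spinal changes sign under the common-sum rescaling, from -0.02 to 0.10 in log2.

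The comparison of T_Spinal with Sham shows what remained different after injury and decoction. Neuron, synapse, myelin and cholesterol synthesis genes were still lower than in Sham, and phagocyte, lysosome, complement, interferon and matrix genes still higher. Snap25 had a log2 fold change of -3.23 (SE 0.0487, adjusted p = 5.63e-12) and Mbp of -1.73 (SE 0.0209, adjusted p = 1.58e-12). Gpnmb reached 1963 ± 36.7 FPKM (SD, n = 3) against 8.48 ± 1.59 in Sham, a change of 7.69 (SE 0.130, adjusted p = 1.17e-11). edgeR called 5171 genes higher and 5409 lower, 2195 and 1929 of them by at least 2-fold, and the groups did not overlap for 9430 genes (63.8%, against 10% by chance). The share of calls that were higher was 48.9%, against 59.7% with limma on log2(FPKM + 1) and 59.6% with total-count scaling. The median log2 fold change of all genes was -0.02 in the reported fit and 0.12 and 0.14 in these.

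Of 24 phagocytic macrophage genes 23 were higher and 1 lower (median 3.89, adjusted p = 1.68e-48), with Mmp12 at 9.35 and Cd68 at 7.66. All 24 neuron genes were lower (median -2.81, adjusted p = 1.31e-37), with Slc6a5 at -3.62, the neurofilament Nefm at -3.41 and Glra1 at -3.40. Lysosomal genes were higher (25 of 29 up, 1 down, median 2.26, adjusted p = 1.31e-37), with the lysosomal growth factor Grn at 3.88 and the protease Ctsz at 3.49. The 5 largest rises under the naming rule, all without counts in any Sham library, were Cxcr1, Vsig4, Ly49s7, RT1-M2 and Atp6v0d2, at least 121-, 112-, 98.0-, 80.6- and 72.4-fold higher in T_Spinal. Vsig4 is a complement receptor of resident macrophages. The largest falls were in Hapln1, a link protein of perineuronal matrix, at -5.16, Fgf18 at -5.01, Sptssb at -4.36, Hmgcs1 at -4.15 and Paqr9 at -4.09. All 24 cholesterol synthesis genes were lower (median -2.70, adjusted p = 1.31e-37), as were all 24 myelin genes (median -1.03, adjusted p = 1.97e-13). All 15 homeostatic microglia genes were higher (median fold 4.004, adjusted p = 1.31e-17), Aif1 among them at 2.92.

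The matrix and scar list (26 of 27 up, 1 down) had a median of 2.66, reactive astrocytes (18 of 18 up) of 2.39, complement (18 of 20 up, 1 down) of 3.57, interferon response (25 of 25 up) of 2.51 and antigen presentation (20 of 20 up) of 2.40. Cytokines and NF-kappaB (27 of 27 up) had 2.52, cell cycle (25 of 27 up, 2 down) 1.84, apoptosis (19 of 26 up, 3 down) 0.89, iron and oxidative stress (15 of 23 up, 6 down) 0.80, meninges (10 of 12 up) 2.42 and ribosomal proteins (49 of 50 up) 0.99. Synaptic genes (33 of 34 down) had -2.22, motor neurons (6 of 6 down) -2.19, homeostatic astrocytes (2 of 17 up, 13 down) -0.59 and oxidative phosphorylation (1 of 33 up, 27 down) -0.39. Neutrophil genes (4 of 4 up) had a fitted median of 6.15, or 3.81 with bounds, and without the expression minimum 7 of 12 were up and 1 down (median 2.49). These lists were called at adjusted p values up to 0.00127, and kept their calls with an estimated correlation, at adjusted p values up to 0.0412. Calls were lost for red blood cells (5 of 6 down, adjusted p = 0.248 with an estimated correlation), adipose tissue (2 of 4 up, 1 down, adjusted p = 0.0562 with an estimated correlation, and 2 of 9 up, 1 down without the minimum) and mitochondrially encoded genes (13 of 13 down, adjusted p = 0.290 with an estimated correlation). Lists without a call were Schwann cells (6 up and 7 down of 16, median 0.06 but test down), immediate early genes (7 and 7 of 18, median 0.16 but test down), the PI3K-AKT core (15 and 21 of 47, median -0.04 but mean 0.25 and test up, adjusted p = 0.267) and bone and cartilage (1 and 3 of 5, median -1.50 but mean 0.67). The others were lymphocytes (2 and 0 of 3), oligodendrocyte precursors (3 and 7 of 12), chondroitin sulfate proteoglycans and growth inhibitors (5 and 16 of 22), regeneration-associated genes (9 and 8 of 21), neurotrophic factors (10 and 8 of 20), glycolysis and hypoxia (7 and 14 of 21), heat shock (11 and 5 of 18), endothelium and pericytes (11 and 4 of 18), ependymal cells (3 and 2 of 11), sensory ganglion neurons (0 and 2 of 3) and skeletal muscle (1 and 3 of 6). Adjusted over the list alone, the counts up and down differed for PI3K-AKT core pathway 16 and 21, lysosome 26 and 1, oxidative phosphorylation 1 and 28, iron and oxidative stress 16 and 6, endothelium and pericytes 12 and 4. Of the fixed genes, Gfap had 0.98, Akt1 0.26 and Bax 0.74, all higher, and Mtor -0.43 and Pik3ca -0.25, both lower. Pik3ca was not called with limma on log2(FPKM + 1) (-0.09) or total-count scaling (-0.10). Bcl2 had 0.26 (adjusted p = 0.404) and Bdnf -0.48 (adjusted p = 0.124). Gap43 had -0.06 (adjusted p = 0.177) and changed sign to a called 0.10 with limma on log2(FPKM + 1) and with total-count scaling, below the medians of all genes given above and with adjusted p values from 0.0180 to 0.542 over the alternatives.

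Genes changed by injury were set beside their change with decoction. Of 5632 genes raised by injury, 2045 (36.3%) fell in T_Spinal against C_Spinal and 543 rose further, where independent lists would share 1009 and 1164. Of 5526 lowered by injury, 2271 (41.1%) rose and 262 fell further, where independent lists would share 1142 and 990.1. In all, 4316 genes moved opposite to injury and 805 along with it. Across the genes tested, the injury and treatment log2 fold changes had a Pearson r of -0.503, a Spearman rho of -0.546 and a covariance of -0.424. Because both contrasts use the C_Spinal libraries, simulated series with no effect had a mean r of -0.501 and covariance of -0.0325, with at most 1 gene called opposite; with the injury effect alone r was -0.0864 and the covariance -0.0325. The observed covariance differed from the simulated by -0.391. In the simulations each library varied on its own, with the fitted spread between libraries of a group. A deviation shared by all C_Spinal libraries was not simulated and would also give opposite calls and a negative covariance. The 3 shared libraries were not split, since 1 contrast would keep a single library of the group, so part of the excess of opposite calls may come from them. On the injury axis, Sham libraries scored 0.0112 ± 0.00992 (SD, n = 3), C_Spinal 0.986 ± 0.00362 and T_Spinal 0.823 ± 0.00136. The difference of T_Spinal from C_Spinal was -0.163, with all 3 libraries below all 3 (exact permutation p = 0.1, the smallest that 3 against 3 allows).

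Positions of the leading genes, as the deposited table lists them without naming a genome build, were Snap25 (ENSRNOG00000006037) on chromosome 3 from 129599353 to 129788400, Mbp (ENSRNOG00000016516) on chromosome 18 from 79326738 to 79437310, Gfap (ENSRNOG00000002919) on chromosome 10 from 90990762 to 90999506 and Thbs1 (ENSRNOG00000045829) on chromosome 3 from 109862117 to 109873466. The table further lists Cx3cr1 (ENSRNOG00000018509) on chromosome 8 from 128740756 to 128754514, Ifit1 (ENSRNOG00000019050) on chromosome 1 from 252944103 to 252946170, Pik3ca (ENSRNOG00000056371) on chromosome 2 from 118831350 to 118861454 and Akt1 (ENSRNOG00000028629) on chromosome 6 from 137218376 to 137236258. All are annotated there as protein-coding genes.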

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

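Most results kept their direction and their side of the threshold. Outside the omission of libraries, 2148 values of single genes were unchanged in this sense, 17 lost and 6 gained a call, and 4 reversed; for lists 657 were unchanged, 31 lost and 5 gained a call. limma on log2(FPKM + 1), DESeq2 and total-count scaling were chosen after seeing the data. Lists were not tested with DESeq2, and with the other pair no list called in the reported fit changed direction; DESeq2 shared 11062, 5539 and 10418 calls with edgeR in the order C_Spinal against Sham, T_Spinal against C_Spinal and T_Spinal against Sham, and limma 10402, 5302 and 9480, of which 9477 had the same direction. A 2-fold minimum, which removes smaller changes by construction, left 2648 and 2271, 234 and 264, and 2195 and 1929 genes higher and lower. The common-sum (TPM-like) rescaling gave 4864 higher and 1574 lower in T_Spinal against C_Spinal, with Akt1 reversed at 0.10; the median of all genes is 0.11 there. Gap43 in T_Spinal against Sham reversed to 0.10 with limma on log2(FPKM + 1), 0.10 with a pseudocount of 0.1 and 0.10 with total-count scaling; the median of all genes is then 0.12 with limma on log2(FPKM + 1) and 0.14 with total-count scaling, against -0.02 in the reported fit. The injury axis score of T_Spinal was 0.826 under the rescaling and 0.834 with injury genes of at least 2-fold, which by their smaller number left 2436 opposite and 317 same-direction genes; the cause of the score's moves was not tested. Leaving out a library at a time gave 5423 to 5629 higher and 5295 to 5533 lower in C_Spinal against Sham, 2591 to 3043 and 2166 to 2706 in T_Spinal against C_Spinal, and 4923 to 5140 and 5115 to 5398 in T_Spinal against Sham. The score was then 0.819 to 0.826, r -0.528 to -0.443, and the opposite and same-direction counts 3682 to 4280 and 618 to 807. Of single genes 23 values lost a call and 1 reversed. The reversed value was the log2 fold change of Crabp2 (second copy), T_Spinal against C_Spinal, at 0 without C_Spinal replicate 3. Without any other library it was fitted at -10.78 to -10.16. T_Spinal had no counts of this copy, so the fitted size is not an estimate and only a lower bound could be given. Of lists 6 lost a call. Libraries with the same number in different groups did not vary together (r of deviations -0.0786 to 0.0920 over 9 pairs, against -0.125 to 0.0730 over 18 others). With a replicate block 10966, 5235 and 10376 genes were called, 10886, 5127 and 10285 of them shared with the reported 11158, 5707 and 10580. With the block, calls between T_Spinal and C_Spinal ended for Mbp (0.07, adjusted p = 0.0563) and for chondroitin sulfate proteoglycans and growth inhibitors (median 0.18, adjusted p = 0.0575), among others. Simulated 1.2-fold changes were recovered in 18% of cases between T_Spinal and C_Spinal and in 10% between T_Spinal and Sham.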

Other observations

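The tests below were chosen after the results they explain were seen, except the regroupings of libraries, and the handling-gene test, whose bounds were written before its ratio was computed.

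KEGG pathways gave further groups. Of 302 pathways, camera called 124 after injury, 54 between T_Spinal and C_Spinal and 136 between T_Spinal and Sham, and 78, 0 and 92 with an estimated correlation. After injury, complement and coagulation (40 of 47 genes up, 3 down, median 2.40) and hematopoietic cell lineage (41 of 50 up, 4 down, median 1.85) rose, and steroid biosynthesis (12 of 14 down, 2 up, median -2.80) and synaptic vesicle cycle (44 of 59 down, 12 up, median -0.95) fell. Between T_Spinal and C_Spinal, neuroactive ligand-receptor interaction had 77 of 150 genes up and 16 down (adjusted p = 0.0669 with an estimated correlation), GABAergic synapse 42 of 78 up and 12 down (adjusted p = 0.0669 with an estimated correlation), and cytochrome P450 drug metabolism 0 up and 18 of 34 down (adjusted p = 0.114 with an estimated correlation).

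Lists differed in how far T_Spinal lay on the way from C_Spinal back to Sham in FPKM. The median over genes was 49.8% for matrix and scar (quartiles 37.3 and 60.0), 51.9% for meninges, 88.8% for Schwann cells, 30.8% for homeostatic astrocytes, 17.8% for myelin, 8.62% for neurons (quartiles 6.86 and 10.7) and 1.10% for cholesterol synthesis. In 12 of 15 homeostatic microglia genes T_Spinal was above both other groups.

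The first pattern is the set of lists that moved between T_Spinal and C_Spinal. A mixture of C_Spinal-like tissue with a share of sham-like tissue would return all lists alike, and the medians of matrix and neuron genes lay 41.2 points apart without overlap of quartiles, which argues against it as the whole cause. Against Sham, the Schwann cell median was 1.03 in C_Spinal and 0.06, without a call, in T_Spinal. The meningeal median was 3.29 and 2.42 in the same order. Less root and meningeal tissue in T_Spinal than in C_Spinal samples could contribute, whichever group's dissection differed. The larger median log2 fold change of the Schwann cell and meningeal lists was -0.88, as this needs, and the labels give no dissected region. It would also raise cord genes alike, and the larger median of the myelin and homeostatic astrocyte lists was 0.29 against 1.02 for neurons; the quartiles of neurons (0.41 and 1.27) overlapped those of astrocytes (0.12 and 0.72) but not those of myelin (0.13 and 0.38), which speaks against this cause for neuron against myelin genes. A difference in dissection and an effect of the decoction therefore cannot be told apart here for these lists, as no sample separates them.

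The next pattern is Ifit1 in T_Spinal. A wider rise of interferon-response genes does not go with the other 24 listed genes, whose median log2 fold change was -0.21 (quartiles -0.33 and 0.04). Reads moved from related genes could contribute. The other 3 Ifit genes lost 74.1% as many normalized counts as Ifit1 gained (Ifit2 37.1%, Ifit3 27.4%, Ifit1bl 9.58%), between the bounds set for and against it. Ifit2 and Ifit3 are among the 24 listed genes with a median of -0.21, so their loss could arise without moved reads. The 74.1% therefore does not decide this. Different genotypes of the rats in each group could also contribute. In all, 70 genes had at least 50 counts in every library of a group and at most 2 in every library of another. Of these, 59 separated C_Spinal from Sham and 47 separated T_Spinal from Sham, and injury itself switches genes on. Injury alone does not account for the 3 that separated T_Spinal from C_Spinal, both injured. AABR07051308 and AABR07044383 had no counts in C_Spinal, and LOC100911166 had none in T_Spinal. AABR07051308 also varied within Sham, with 234, 0 and 7 counts in replicates 1, 2 and 3. Its counts can thus differ without a difference between groups. Ifit1 was also the listed interferon-response gene that fell after injury, at -3.71. An effect of the decoction on Ifit1 remains among the open explanations, untested.

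The last pattern is the small spread between libraries of a group, with a median coefficient of variation of 4.43% in Sham, 4.28% in C_Spinal and 4.51% in T_Spinal among highly counted genes. Immediate early, stress hormone and hemoglobin genes, which vary with handling and blood between animals, had a median ratio of 1.08 (quartiles 0.692 and 1.46, 27 genes) to genes of like count. Single blood genes went both ways, such as Hbb at 2.82 in Sham, 0.372 in C_Spinal and 0.523 in T_Spinal, and Alas2 at 0.110, 2.09 and 1.03, with reads of the hemoglobin genes partly shared. The median is consistent with libraries of a group made from 1 RNA sample, which needed a ratio of 1.2 or less. Single genes could differ more within a group, such as Tctn3 with 424, 101 and 0 counts in T_Spinal replicates 1, 2 and 3. In the same replicates LOC100911374 had 248, 195 and 0 counts and LOC103690149 had 0, 0 and 181. RGD1565462 had 0, 170 and 99 in C_Spinal, and AABR07051308 had 234, 0 and 7 in Sham. The cause of these differences was not tested. Libraries made from pooled animals could give the same 4.43%, and no value here decides between 1 RNA sample, pools or alike animals.

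The 6 libraries of a contrast can be split in 10 ways, too few for a share under 0.05. The real split called 11158, 5707 and 10580 genes in C_Spinal against Sham, T_Spinal against C_Spinal and T_Spinal against Sham, and the highest other split called 1 in each, so that 1 split of 10 gave as many.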
